A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

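RNA sequencing was performed on rabbit ear skin in 3 groups of 3 libraries: normal skin, untreated acne tissue and acne tissue treated with microneedles. Per the labels' protocols, acne was induced with 0.5 mL of 50% oleic acid on the ear each day for 14 days, with 100 µL injections of a suspension of the skin bacterium C. acnes every other day from day 10. The microneedles, named HMC-PEP MN in the labels, were then applied to the acne area once daily, 5 applications in all, and the animals were euthanised on day 7. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. Samples were assigned to groups by their titles, which also number the replicates. The labels do not say that the replicates of a group came from separate animals, so the p-values measure only the spread between these samples.

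The deposited table holds 1 FPKM value (fragments scaled by gene length and by library total) per gene and library, with a gene symbol or identifier, a description and Gene Ontology (GO) and KEGG pathway terms. It has 23373 genes, 19450 of them protein-coding, and 8259 carry an identifier beginning with LOC in place of a symbol. GO terms are given for 16870 genes and KEGG pathways for 7743. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.0, HTSeq 0.11.2, R 3.2.0 and DESeq2 1.22.2 without saying what each was used for. The genome build and the annotation release are not given in the sources used here, and no coordinates were used. Whether the counting used strand is not given in the sources used here either, so overlapping and antisense genes cannot be told apart.

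FPKM values are not counts, so no count test was the main test. Because each low value is a whole multiple of the value of 1 fragment, the fragments behind the table could be recovered: for 23373 genes (100%) the values of all 9 libraries came out whole within a tolerance of 1e-05. The 9 libraries held 28976412 to 34675686 counted fragments, with a largest gap of 0.024% between the totals and the step sizes. A further check compared libraries within groups by chi-square over recovered fragments, among genes with at least 20 fragments in a pair. Chi-square per degree of freedom ran from 13.6 to 122.5, so no library was a copy of another within sampling noise.

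Genes were tested when their FPKM reached 0.5 in at least 3 of the 9 libraries, which left 14151 genes (60.5%). Values were taken as log2(FPKM + 1) with no further scaling. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 9 libraries, with 6 residual degrees of freedom, and empirical Bayes moderation with a mean-variance trend and robust estimation. Benjamini-Hochberg adjustment ran over all genes tested in a comparison, and a gene passed at an adjusted p under 0.05 with no fold threshold. Fold changes are differences of mean log2(FPKM + 1), which understates the change of genes with low FPKM. The smallest p that an exact permutation test of 3 libraries against 3 can give is 0.1, so single genes were tested with limma alone. On simulated values for 13846 genes, 66, 65 and 66 genes were changed 1.5-fold, 2-fold and 4-fold in microneedle tissue. Against untreated acne the procedure recovered 62.1%, 90.8% and 100% of them, with 9 false calls. For microneedle tissue against normal skin it recovered 60.6%, 90.8% and 98.5%, with 8 false calls, and for acne against normal skin, where no gene was changed, it made 1 false call. Far fewer genes changed there than passed in the data, and all libraries had the same spread, so these rates need not hold for the data.

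A total of 39 gene lists with 868 entries, the rule for naming genes and the designs were fixed before the data were examined. Of the entries, 703 matched a symbol in the table, 47 matched through the symbols and synonyms of the RefSeq gene table of rabbit assembly mOryCun1.1, 114 were not matched and 4 repeated a gene already matched. That table held 20429 of the NCBI gene identifiers. Lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 38 lists with at least 5 tested members. Each list was also tested with a correlation estimated from the data and with fry. Passing members were counted over all genes tested and also adjusted over the list alone. A list score is the median over tested members of log2(FPKM + 1) minus the gene's mean over the 9 libraries. GO and KEGG terms with 10 to 500 tested members were tested among the genes higher or lower in a comparison with a one-sided Fisher exact test. The background was the 12851 tested genes with any term, and adjustment ran over 2626 terms per comparison and direction.

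The named genes followed a rule. For acne against normal skin and for microneedle tissue against untreated acne, they are the 6 higher and 6 lower genes with the largest absolute fold change. These had to pass the test, carry a symbol, have a mean FPKM of at least 2 in the higher group and show no overlap between the groups' libraries. A fixed panel of 18 genes of inflammation, lipid metabolism, epidermis and matrix was added, with the 2 members of smallest p in each list that passed. For microneedle tissue against normal skin the rule took 4 genes in each direction and the list members. Apart from the panel, the rule therefore picked genes from these results by their fold change or p, so their values are selected extremes. Any other gene named was chosen after its values were seen, without a rule.

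Comparisons of acne with normal skin and of microneedle tissue with untreated acne share the 3 untreated libraries. The overlap of their calls was therefore set beside the overlap of independent lists and beside 20 simulations with unchanged groups. Alternatives covered pseudocounts of 0.1 and 0.5, other filters on low values (a value above 0, a mean FPKM of at least 1, FPKM of at least 5 in 3 libraries), rescaling to TPM, median-of-ratios scaling, quantile normalization, array quality weights, moderation without trend, only the 6 libraries compared, the replicate number as a block, stricter thresholds and leaving out each library. Testing the recovered fragments with voom and leaving out genes that share a description with another gene were added after the data were seen. The latter setting also left out the mitochondrially encoded genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, term tests and figures. FASN and SCD were not matched in the table and are not analysed here.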

Results

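Gene expression was measured by RNA sequencing in rabbit ear skin, a standard site for modelling acne because oily treatment of the ear canal opening gives comedone-like lesions. The 9 libraries comprised 3 of normal skin, 3 of untreated acne tissue and 3 of acne tissue treated with microneedles, which are arrays of short needles that cross the outer skin layer. According to the labels, the study asked what the microneedles do to acne, with inflammation and lipid metabolism as its themes. The libraries held 28976412 to 34675686 counted fragments, and 14151 genes were tested. Libraries of 1 group correlated at 0.972 to 0.995 (Pearson's r across genes, which are not independent replicates) and libraries of different groups at 0.873 to 0.964. A principal component analysis placed 64.3% of the variance on a first component that separated normal skin, at scores from −63.9 to −61.8, from all 6 acne libraries, at 24 to 44.7. The second component, with 21.8%, separated untreated acne, at −34.2 to −31.3, from microneedle tissue, at 17 to 37.1. Microneedle replicate 3 stood apart from the other 2 microneedle libraries on the third component, at 33 against −6.4 and −15.7. The root mean square log2 difference between group means was 0.814 for acne against normal skin, 0.531 for microneedle tissue against untreated acne and 0.858 for microneedle tissue against normal skin.

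The first comparison asked how untreated acne tissue differed from normal ear skin. Acne tissue carried a broad immune signature, and most tested cornified envelope genes were higher, while most tested markers of cartilage, nerve and smooth muscle were lower. As lists these calls rest on the preset correlation between genes, and none held with an estimated correlation. Serum amyloid A-3 (SAA3), an acute-phase protein, stood at 8021 ± 682 FPKM in acne and 13.7 ± 11.6 in normal skin (mean ± SD, n = 3 libraries per group, as for all values given this way). Its log2 fold change was 9.36 (limma adjusted p = 2.67e-07). S100A8, a calcium-binding alarm protein of neutrophils and stressed keratinocytes, stood at 1605 ± 208 against 3.06 ± 2.17 FPKM (log2 fold change 8.76, adjusted p = 8.5e-07). Keratin 16 (KRT16), a keratin of activated epidermis, stood at 456 ± 55.8 against 15.2 ± 3.87 FPKM (log2 fold change 4.84, adjusted p = 1.23e-05). The small heat shock protein CRYAB was lower, at 46.0 ± 6.45 against 557 ± 116 FPKM (log2 fold change −3.56, adjusted p = 1.47e-06). So was GREM1, a secreted antagonist of bone morphogenetic proteins, at 13.4 ± 4.24 against 144 ± 49.6 FPKM (log2 fold change −3.32, adjusted p = 8.29e-06). In all, 2922 genes were higher and 3245 lower in acne (43.6% of those tested), of which 1028 and 731 differed at least 2-fold. Rescaling to TPM moved the median log2 fold change of all tested genes from −0.04 to −0.21 and the calls to 2312 higher and 4869 lower, 32.2% higher in place of 47.4%. Median-of-ratios scaling (3124 higher and 2926 lower, 51.6% higher) and voom on the recovered fragments (3119 and 2855, 52.2%) turned the balance the other way.

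Inflammatory gene lists moved upward together in acne tissue. Of 21 tested proinflammatory cytokines and chemokines, 13 rose (13 adjusted over the list alone) and 8 did not pass, with a median log2 fold change of 1.80 (camera adjusted p = 4.33e-07, adjusted p = 0.216 with an estimated correlation). Interleukin 1 alpha (IL1A), a cytokine released by damaged keratinocytes, stood at 20.8 ± 5.55 against 1.10 ± 0.0873 FPKM, and the B cell survival factor TNFSF13B at 14.7 ± 2.53 against 0.585 ± 0.283 FPKM. Among regulators that restrain inflammation, 10 of 16 rose (10 adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.142 with an estimated correlation). They included the interleukin 1 receptor antagonist IL1RN at a log2 fold change of 2.93 and the TNF receptor TNFRSF1B at 1.71. Toll-like receptor, NF-kB and inflammasome components, which sense microbes and start inflammation, rose in 14 of 21 cases (14 adjusted over the list alone, camera adjusted p = 1.08e-05, adjusted p = 0.0673 with an estimated correlation). CD14, the co-receptor for bacterial products, stood at 196 ± 14.0 against 14.1 ± 1.57 FPKM, and TLR2, a receptor for bacterial lipoproteins, at 6.50 ± 0.127 against 1.18 ± 0.0543 FPKM (adjusted p = 5.52e-07). Interferon-stimulated genes rose in 15 of 17 cases (15 adjusted over the list alone, camera adjusted p = 8.87e-08, adjusted p = 0.179 with an estimated correlation). Among them was an OAS3-like gene (LOC100340530), at a log2 fold change of 2.09. Of 11 epidermal antimicrobial and alarm genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000462, adjusted p = 0.287 with an estimated correlation). The member that fell was a lysozyme C gene (LOC100341160), at 0.532 ± 0.144 against 13.4 ± 1.56 FPKM. Of 14 complement components, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 5.53e-05, adjusted p = 0.0759 with an estimated correlation). The receptor C5AR1 had a log2 fold change of 2.74 and the central component C3 of 1.68.

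Markers of every major leukocyte class tested, mast cells apart, were higher in acne tissue. Neutrophil markers rose in 13 of 14 cases (13 adjusted over the list alone), with a median log2 fold change of 2.27 (camera adjusted p = 1.18e-09, adjusted p = 0.0673 with an estimated correlation). The oxidase subunit neutrophil cytosolic factor 1 (LOC100008803) stood at 6.93 ± 0.478 FPKM, against 0.296 ± 0.0976 in normal skin. Macrophage and monocyte markers rose in 16 of 18 cases and fell in 1, the lysozyme C gene (16 and 1 adjusted over the list alone, median 2.58, camera adjusted p = 1.18e-09, adjusted p = 0.0759 with an estimated correlation). CD68, a lysosomal glycoprotein of macrophages, stood at 233 ± 17.9 against 22.8 ± 2.85 FPKM. T and natural killer cell markers rose in 16 of 17 cases (17 adjusted over the list alone, median 1.77, camera adjusted p = 1.19e-11, adjusted p = 0.0803 with an estimated correlation). The cytotoxic protease GZMA had a log2 fold change of 3.08 and the T cell receptor subunit CD3E of 2.78. For B and plasma cell markers the count was 9 of 10 (10 adjusted over the list alone, median 2.28, camera adjusted p = 3.96e-08, adjusted p = 0.113 with an estimated correlation). JCHAIN, which joins IgA and IgM subunits, stood at 1645 ± 340 against 11.5 ± 0.144 FPKM, and the B cell receptor CD22 had a log2 fold change of 2.09. Dendritic and Langerhans cell markers rose in 10 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone, median 1.38, camera adjusted p = 2.97e-05, adjusted p = 0.113 with an estimated correlation). The integrin ITGAX rose by 2.75 on the log2 scale and the antigen presentation chaperone CD74 by 2.50. Of 7 mast cell markers 1 fell, the transcription factor GATA2, and the list did not pass (camera adjusted p = 0.707).

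In the epidermis lists, 13 of 21 cornified envelope and terminal differentiation genes rose and 2 fell (13 and 3 adjusted over the list alone, median 1.01, camera adjusted p = 0.000106, adjusted p = 0.411 with an estimated correlation). Caspase 14 (CASP14), a protease of cornification, stood at 299 ± 59.6 against 35.0 ± 8.49 FPKM, and the barrier lipid transporter ABCA12 at 29.2 ± 2.27 against 7.24 ± 1.56 FPKM. Hyperproliferation-associated keratinocyte genes rose in 6 of 13 cases and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.291 with an estimated correlation). KRT16 and the serpin SERPINB2, at a log2 fold change of 1.42, led that list, whose call ended with a filter of FPKM of at least 5 (adjusted p = 0.0862). Basal keratinocyte markers did not pass, with 3 of 11 higher and 2 lower (camera adjusted p = 0.917). Cell cycle genes rose in 20 of 26 cases (21 adjusted over the list alone, median 0.80, camera adjusted p = 5e-07, adjusted p = 0.411 with an estimated correlation). The proliferation marker MKI67 stood at 7.15 ± 0.31 against 2.22 ± 0.226 FPKM and the mitotic ubiquitin enzyme UBE2C at 16.6 ± 0.414 against 6.05 ± 1.66 FPKM. Matrix proteases and inhibitors rose in 13 of 20 cases and fell in 3 (14 and 3 adjusted over the list alone, median 1.17, camera adjusted p = 1.08e-05, adjusted p = 0.0759 with an estimated correlation). The collagenase MMP1 stood at 142 ± 23.1 against 2.15 ± 0.708 FPKM, the lysosomal protease cathepsin S (CTSS) at 343 ± 21.5 against 36.5 ± 3.27, and the gelatinase MMP9 at 4.60 ± 0.594 against 0.317 ± 0.137 (adjusted p = 3.89e-06).

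Lipid genes divided. Of 22 genes of fatty acid and triglyceride synthesis, 12 fell and 4 rose (12 and 4 adjusted over the list alone), with a median log2 fold change of −0.46 (camera adjusted p = 0.0413, adjusted p = 0.411 with an estimated correlation). The desaturase SCD5 fell from 13.9 ± 3.24 to 2.75 ± 0.173 FPKM (adjusted p = 3.79e-06), and SREBF1, the transcription factor that drives fatty acid synthesis genes, from 32.7 ± 3.35 to 19.1 ± 1.07 FPKM (log2 fold change −0.74, adjusted p = 2e-04). ELOVL1, which elongates very long-chain fatty acids, rose from 92.6 ± 5.25 to 211 ± 23.6 FPKM. The list's call ended without normal skin replicate 1 (adjusted p = 0.0672) and without acne replicate 1 (adjusted p = 0.0782), as it did with TPM rescaling, quantile normalization, array weights, either stricter filter or only the 6 libraries compared (0.0509 to 0.0687). ACACA, the first committed enzyme of fatty acid synthesis, had a log2 fold change of −0.28 (adjusted p = 0.0459). Its call ended without any 1 of the 6 libraries, with adjusted p = 0.0767, 0.0578 and 0.144 without normal skin replicates 1, 2 and 3 and 0.164, 0.0749 and 0.103 without acne replicates 1, 2 and 3. It also ended with median-of-ratios scaling (adjusted p = 0.0639). PPARG, a transcription factor of sebocytes and fat cells, stood at 9.09 ± 0.878 against 12.7 ± 2.74 FPKM (adjusted p = 0.0547) and the triglyceride enzyme DGAT2 at 100 ± 11.5 against 150 ± 61.5 FPKM (adjusted p = 0.0987). Both passed without normal skin replicate 2 (0.013 for PPARG, 0.0219 for DGAT2) and with TPM rescaling (0.00906 and 0.0186). Without normal skin replicate 1, which had 219 FPKM of DGAT2 against 103 and 126 in the other normal libraries, the log2 fold change of DGAT2 was −0.19 in place of −0.50 (adjusted p = 0.258) and that of PPARG −0.30 in place of −0.43 (0.17).

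Other lipid lists did not pass in acne against normal skin. Sebocyte and sebaceous gland markers split into 6 higher and 3 lower of 16 (camera adjusted p = 0.751). Cholesterol synthesis and uptake had 3 higher and 2 lower of 22 (0.729), fatty acid oxidation and peroxisomal genes 4 and 1 of 21 (0.186) and lipid droplet, lipolysis and adipocyte genes 2 and 7 of 13 (0.172). Steroid, retinoid and insulin-like growth factor signalling had 3 higher and 5 lower of 19 (0.751). Chosen after their values were seen, the sebaceous gland genes MC5R and CIDEA fell by 2.49 and 2.16 on the log2 scale, and the fat cell genes FABP4 and LEP by 1.94 and 1.97. Of the same sebaceous list, ELOVL3 rose by 1.56 on the log2 scale and FAR2 from 27.9 ± 7.08 to 79.8 ± 15.7 FPKM, also chosen after their values were seen. The median, the mean and the test differed in sign for sebocyte markers (median 0.08, mean −0.14, test upward) and for basal keratinocyte markers (median −0.04, mean 0.09, test upward).

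Cartilage markers were the most lowered list in acne tissue: 14 of 16 fell (14 adjusted over the list alone), with a median log2 fold change of −2.30 (camera adjusted p = 2.24e-06, adjusted p = 0.346 with an estimated correlation). The link protein HAPLN1 stood at 17.3 ± 4.17 against 87.4 ± 10.6 FPKM, the chondrocyte proteoglycan SNORC at 10.3 ± 2.18 against 108 ± 22.2, and the cartilage collagen COL9A1 at 7.94 ± 2.73 against 83.7 ± 25.0. Schwann cell and nerve markers fell in 11 of 12 cases and rose in 1 (11 and 1 adjusted over the list alone, median −1.92, camera adjusted p = 2.97e-05, adjusted p = 0.291 with an estimated correlation). S100B, a marker of Schwann cells and chondrocytes, stood at 17.8 ± 6.09 against 173 ± 30.2 FPKM, and the Schwann cell transcription factor SOX10 at 1.46 ± 0.0397 against 7.84 ± 0.92. Smooth muscle and pericyte markers fell in 8 of 13 cases (9 adjusted over the list alone, median −1.19, camera adjusted p = 0.0011, adjusted p = 0.411 with an estimated correlation). The pericyte proteoglycan CSPG4 had a log2 fold change of −1.64 and the contractile protein LMOD1 of −2.14. Normal skin replicate 1 scored 0.07 on that list, against 1.30 and 1.18 in the other normal libraries. The ear is built on a cartilage plate, and the labels do not give the depth of the tissue pieces.

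The remaining lists did not pass in this comparison. Fibrillar collagen and matrix genes had 2 higher and 6 lower of 20 (camera adjusted p = 0.188), with COL1A1 at 3950 ± 409 against 4561 ± 201 FPKM (limma adjusted p = 0.273, and 0.0466 with TPM rescaling and 0.00143 with quantile normalization). Proteoglycans and hyaluronan genes had 6 higher and 9 lower of 23 (0.34), and angiogenesis and growth factor genes 1 and 7 of 21 (0.148), with VEGFA at 27.2 ± 3.82 against 30.9 ± 5.16 FPKM. Antioxidant and NRF2 target genes had 9 higher and 4 lower of 22 (0.249), endothelial and lymphatic markers 5 and 8 of 18 (0.638), and hair follicle markers 4 and 1 of 10 (0.277). Skeletal muscle markers had 2 higher and 4 lower of 7 (0.135) and melanocyte markers 1 and 5 of 8 (0.249). Cytoplasmic ribosomal proteins had 1 higher and 3 lower of 70 (0.917), nuclear oxidative phosphorylation genes 2 and 3 of 27 (0.659), and immediate early and heat shock genes 4 higher of 17 (0.34). Of 4 tested erythrocyte genes, too few for the list test, 3 were lower, with a median log2 fold change of −0.78.

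Among the panel cytokines, TNF stood at 2.23 ± 0.349 against 0.16 ± 0.0584 FPKM (log2 fold change 1.47, limma adjusted p = 0.0101) and transforming growth factor beta 1 (TGFB1) at 30.8 ± 1.38 against 13.6 ± 0.029 (1.12, adjusted p = 4.98e-05). Interleukin 1 beta (IL1B) stood at 3.78 ± 1.15 against 0.376 ± 0.104 FPKM (adjusted p = 0.0252). That call ended without normal skin replicates 1, 2 or 3 (0.0609, 0.0584 and 0.0701), without acne replicates 1 or 2 (0.0742 and 0.0787) and with voom on the recovered fragments (0.104). Interleukin 6 (IL6), at 1.65 ± 0.913 against 0.282 ± 0.187 FPKM (adjusted p = 0.325), and the neutrophil attractant CXCL8, at 8.49 ± 1.33 against 2.78 ± 0.66 (adjusted p = 0.209), did not pass with the spread shared over 9 libraries. Both passed when only the 6 libraries compared were used (0.00854 and 0.000367), and CXCL8 also with array weights (0.0246). IL17A lay below the filter in all 9 libraries, at 0 to 0.139 FPKM. Enrichment tests gave 179 terms among the higher and 63 among the lower genes. Innate immune response had 113 of 213 members higher (43.8 from chance, Fisher exact adjusted p = 1.18e-22) and lysosome 63 of 119 (24.5 from chance, adjusted p = 5.55e-13). Among the lower genes were chondrocyte differentiation, 16 of 24 (5.46 from chance, adjusted p = 0.0018), and regulation of lipolysis in adipocytes, 23 of 44 (10 from chance, adjusted p = 0.00377).

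**Figure D1:**
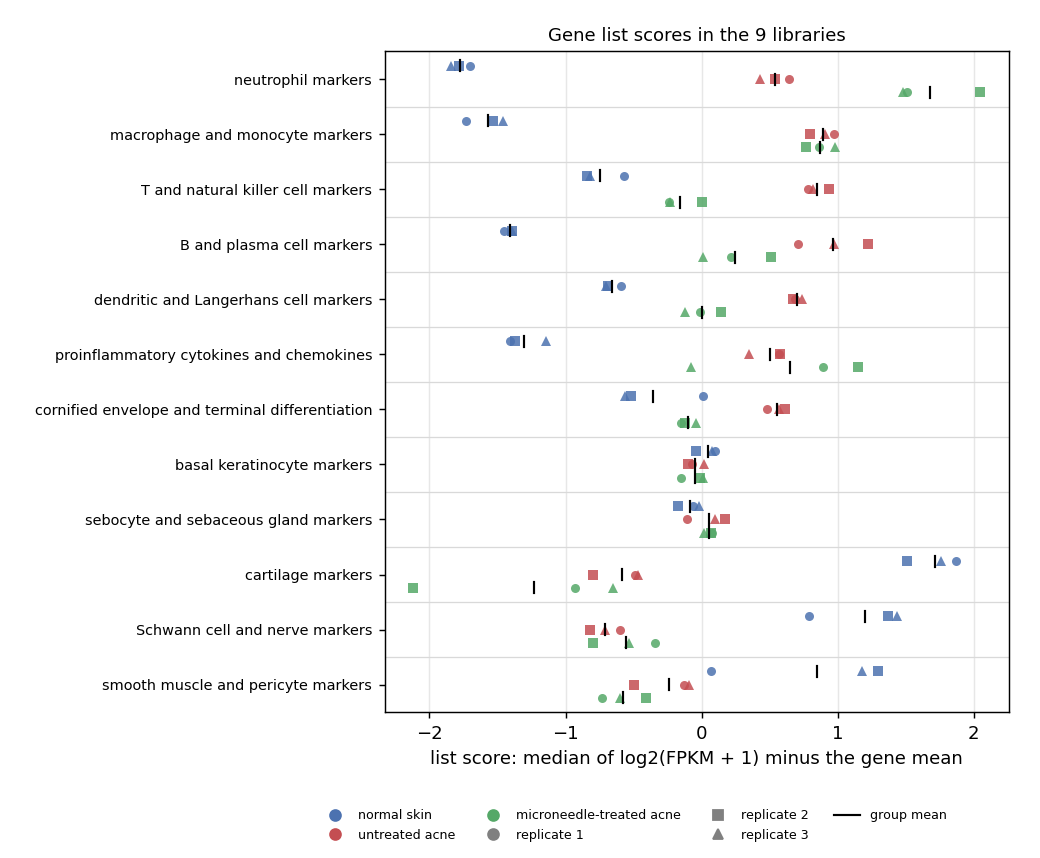
List scores in each library for 12 gene lists, where a point is the median over list members of log2(FPKM + 1) minus the gene's mean over 9 libraries, colour gives the group, shape the replicate and the black bar the group mean. Neutrophil scores lie at −1.84 to −1.70 in normal skin, 0.43 to 0.64 in untreated acne and 1.48 to 2.05 in microneedle tissue, while T and natural killer cell scores lie at 0.78 to 0.94 in untreated acne and −0.24 to 0 in microneedle tissue.

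Mitochondrially encoded genes differed between the groups in an uneven way. Between acne and normal skin, 11 of 13 rose (11 adjusted over the list alone), with a median log2 fold change of 5.98 (camera adjusted p = 5.37e-11, adjusted p = 0.0803 with an estimated correlation). Among subunits of the respiratory chain, ATP8 stood at 6712 ± 1049 against 4.02 ± 5.36 FPKM, COX1 at 1498 ± 226 against 2.88 ± 1.71, COX2 at 8450 ± 847 against 30.8 ± 7.35 and ND1 at 1297 ± 165 against 1.53 ± 1.34. Cytochrome b (CYTB) and ND4, of the same chain and the same small genome, stood at 5695 ± 659 against 6078 ± 387 and at 881 ± 131 against 813 ± 133 FPKM. The 13 genes held 0.98 to 1.08% of counted fragments in normal skin, 2.75 to 3.47% in untreated acne and 1.36 to 1.45% in microneedle tissue. Near-identical copies of mitochondrial genes lie in mammalian nuclear genomes, so how fragments were divided between copies makes these values uncertain. The same holds for lactate dehydrogenase A (LDHA), a glycolytic enzyme, at 0.663 ± 0.095 FPKM in acne against 88.3 ± 21.8 in normal skin and 149 ± 6.55 in microneedle tissue. The other gene with that description stood at 157 ± 20.5, 80.2 ± 16.9 and 128 ± 13.9 FPKM in those groups.

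**Figure D2:**
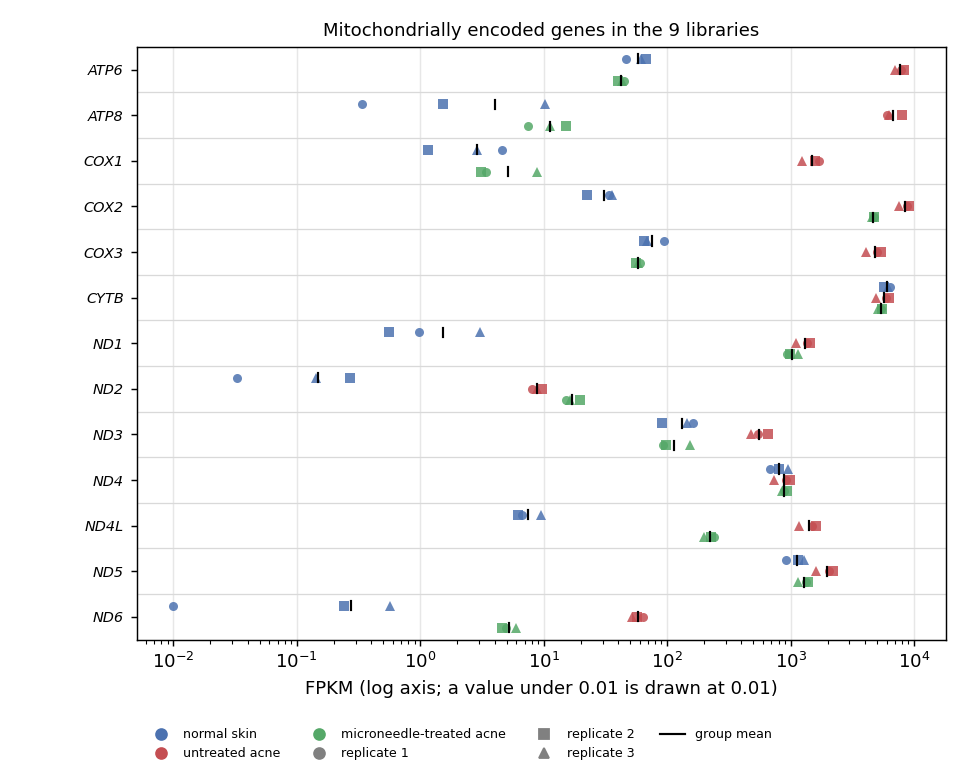
FPKM on a log axis of the 13 mitochondrially encoded genes in each library, with colour for the group, shape for the replicate and a black bar for the group mean. CYTB, ND4 and ND5 lie within 682 to 6421 FPKM in all 9 libraries, while ATP8 reaches 5990 to 7915 FPKM in untreated acne and 0.338 to 15.0 FPKM in the other libraries.

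The second comparison asked how microneedle treatment changed acne tissue. Most tested neutrophil and antimicrobial genes were higher after treatment, and most tested T, B and dendritic cell markers and genes of the cornified layer were lower. As lists these calls rest on the preset correlation between genes, with adjusted p = 0.336 to 0.68 with an estimated correlation. CXCL8 reached 264 ± 201 FPKM against 8.49 ± 1.33 in untreated acne (log2 fold change 4.16, limma adjusted p = 0.00576), and lactotransferrin (LTF), an iron-binding protein of neutrophil granules, 11.3 ± 5.96 against 0.0461 ± 0.0299 FPKM (3.40, adjusted p = 0.000138). The chemokine GRO-A stood at 98.2 ± 71.6 against 7.64 ± 2.42 FPKM (3.04, adjusted p = 0.0133) and MMP9 at 32.9 ± 6.86 against 4.60 ± 0.594 (2.58, adjusted p = 3.94e-06). GRO-A was uneven within the microneedle group, at 145 and 134 FPKM in replicates 1 and 2 and 15.7 in replicate 3. Its log2 fold change ran from 2.50 to 4.06 when 1 library was left out (highest limma adjusted p = 0.0439). Granzyme A (GZMA) fell to 1.70 ± 0.445 from 8.09 ± 1.40 FPKM (−1.75, adjusted p = 4.94e-05). Osteocalcin (BGLAP), a bone matrix protein, fell to 0.303 ± 0.319 from 13.4 ± 3.11 FPKM (−3.47, adjusted p = 1.52e-05). In all, 1907 genes were higher and 2222 lower (29.2%), of which 261 and 367 differed at least 2-fold. Leaving out 1 library moved these counts by more than 1.5 times in 4 cases, to 1123 higher and 1402 lower without acne replicate 1, 1072 and 1313 without acne replicate 2, 1215 and 1424 without acne replicate 3, and 1106 and 1292 without microneedle replicate 1.

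Neutrophil markers rose in 8 of 14 cases and fell in 1 (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.92 (camera adjusted p = 6.6e-05, adjusted p = 0.336 with an estimated correlation). The granulocyte growth factor receptor CSF3R stood at 8.64 ± 0.709 against 0.489 ± 0.0377 FPKM. Chosen after their values were seen, the chemokine receptors CXCR1 and CXCR2 had log2 fold changes of 1.58 and 1.06. Epidermal antimicrobial and alarm genes rose in 7 of 11 cases and fell in 1 (7 and 1 adjusted over the list alone, median 1.12, camera adjusted p = 0.000723, adjusted p = 0.52 with an estimated correlation). The lysozyme C gene (LOC100341160) led that list at 376 ± 38.5 against 0.532 ± 0.144 FPKM, while 3 other genes with its description together stood at 116 ± 42.6 against 21.2 ± 6.11. The antimicrobial list shares S100A8, S100A9, S100A12 and LTF with the neutrophil list, so the results of these lists are not independent in any comparison. S100A8 did not pass, at 1874 ± 965 against 1605 ± 208 FPKM (adjusted p = 0.912). The median of the antimicrobial list was 0.69 without microneedle replicate 2 and 0.58 without genes that share a description with another gene, and its call ended with a filter of FPKM of at least 5 (adjusted p = 0.0745).

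Lymphocyte markers moved the other way. T and natural killer cell markers fell in 15 of 17 cases (17 adjusted over the list alone), with a median log2 fold change of −1.05 (camera adjusted p = 1.69e-11, adjusted p = 0.336 with an estimated correlation). The T cell co-stimulator ICOS stood at 0.214 ± 0.0972 against 2.31 ± 0.41 FPKM (adjusted p = 2.86e-05). B and plasma cell markers fell in 8 of 10 cases (9 adjusted over the list alone, median −0.85, camera adjusted p = 0.000577, adjusted p = 0.52 with an estimated correlation). The B cell co-activator POU2AF1 stood at 2.18 ± 0.981 against 8.59 ± 2.46 FPKM and the plasma cell transcription factor XBP1 at 147 ± 23.2 against 270 ± 27.7. Dendritic and Langerhans cell markers fell in 9 of 14 cases and rose in 1 (9 and 1 adjusted over the list alone, median −0.56, camera adjusted p = 0.00275, adjusted p = 0.52 with an estimated correlation). CD83, a marker of mature dendritic cells, stood at 0.0273 ± 0.0136 against 2.74 ± 0.587 FPKM, and CIITA, which switches on class II antigen presentation genes, at 1.62 ± 0.467 against 5.01 ± 0.105. With a filter of FPKM of at least 5 the dendritic list had a median of 0.04 and no call (adjusted p = 0.893). Macrophage and monocyte markers split into 4 higher and 4 lower of 18 and did not pass (camera adjusted p = 0.758), with CD68 at 232 ± 15.8 against 233 ± 17.9 FPKM. Enriched among the lower genes were the intestinal immune network for IgA production, 26 of 39 (5.93 from chance, Fisher exact adjusted p = 1.31e-09), and antigen processing and presentation, 26 of 61 (9.28 from chance, adjusted p = 6.4e-05).

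Interferon-stimulated genes fell in 6 of 17 cases and rose in 1 (8 and 1 adjusted over the list alone, median −0.41, camera adjusted p = 0.0302, adjusted p = 0.733 with an estimated correlation). The antiviral GTPase MX1 stood at 12.3 ± 0.944 against 18.4 ± 0.526 FPKM and IFI44 at 7.35 ± 0.788 against 13.9 ± 0.866. This call ended without acne replicate 1 (adjusted p = 0.0758), without microneedle replicate 3 (0.125), with array weights (0.102) and without genes that share a description (0.0554). The proinflammatory cytokine and chemokine list did not pass (camera adjusted p = 0.647), with 4 of 21 members higher and 8 lower (5 and 8 adjusted over the list alone). Its median was 0.08 and its mean 0.22 while the test pointed downward. The libraries of the microneedle group differed: the list score was 0.89 and 1.15 in microneedle replicates 1 and 2, above the untreated range of 0.35 to 0.58. In microneedle replicate 3 it was −0.08, below that range. IL1A was lower, at 6.53 ± 0.439 against 20.8 ± 5.55 FPKM (adjusted p = 0.000189). Chosen after their values were seen, the T cell attractants CXCL10 and CXCL11 fell by 2.19 and 1.85 on the log2 scale, and the monocyte and T cell attractant CCL4 rose by 2.25 (adjusted p = 0.043). In CCL4 microneedle replicates 1 and 2 carried the rise, at 69.9 and 61.8 FPKM, while replicate 3, at 6.95, lay within the untreated range of 4.24 to 8.8. IL1B reached 17.4 ± 13.4 FPKM against 3.78 ± 1.15 (log2 fold change 1.63, adjusted p = 0.0487). That call ended without acne replicates 1, 2 or 3 (0.0971, 0.0893 and 0.127), without microneedle replicates 1 or 2 (0.125 and 0.106), without a filter (0.0823), with TPM rescaling (0.0503), with the 6 libraries alone (0.088) and with voom (0.0952). The log2 fold change of IL1B was 1.06 without microneedle replicate 2.

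Several panel genes did not pass between microneedle and untreated acne tissue. IL6 stood at 6.46 ± 6.79 against 1.65 ± 0.913 FPKM (limma adjusted p = 0.411), TNF at 2.86 ± 1.97 against 2.23 ± 0.349 (0.885), KRT16 at 621 ± 322 against 456 ± 55.8 (0.619) and TLR2 at 5.25 ± 0.482 against 6.50 ± 0.127 (0.0707). Microneedle replicate 3 was the lowest of its group in IL6, TNF, KRT16, CXCL8 and IL1B, with 0.0787 FPKM of IL6 and 31.9 FPKM of CXCL8, against 5.71 and 13.6 and against 378 and 381 in the other 2 libraries. The log2 fold change of IL6, 0.89 with all libraries, was 0.07 without microneedle replicate 2 (adjusted p = 0.944). Without microneedle replicate 3, IL6 was higher (log2 fold change 1.95, adjusted p = 0.00237), TNF was higher (0.63, 0.00336), KRT16 was higher (0.81, 0.0119) and TLR2 was lower (−0.31, 0.029). TNF, KRT16 and S100A8 had the opposite sign without microneedle replicate 2, at −0.22, −0.07 and −0.29. TNF and S100A8 had it also without microneedle replicate 1 (−0.16 and −0.02), TNF without acne replicate 3 (−0.01) and S100A8 without acne replicate 1 (−0.02). TGFB1 stood at 29.4 ± 4.96 against 30.8 ± 1.38 FPKM (0.66) and VEGFA at 32.4 ± 5.09 against 27.2 ± 3.82 (0.273). COL1A1 stood at 3161 ± 586 against 3950 ± 409 FPKM (log2 fold change −0.33, adjusted p = 0.113), with the opposite sign after quantile normalization (0.13) and a range of −0.46 to −0.19 when 1 library was left out. TGFB1, at −0.08, had the opposite sign without microneedle replicate 3 (0.07) and with array weights (0.03).

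**Figure D3:**
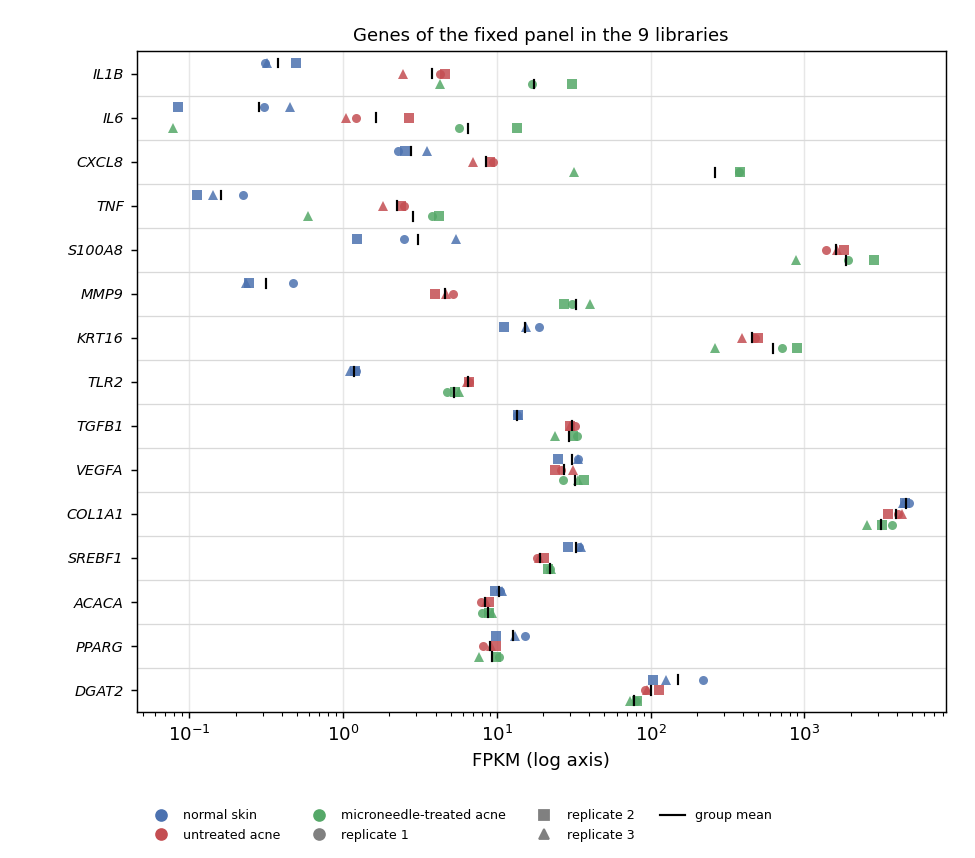
FPKM on a log axis of the 15 panel genes tested, 1 point per library, with colour for the group, shape for the replicate and a black bar for the group mean. CXCL8 lies at 2.28 to 3.53 FPKM in normal skin, 6.98 to 9.49 in untreated acne and 31.9 to 381 in microneedle tissue, where replicate 3 is the lowest.

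In the epidermis, cornified envelope and terminal differentiation genes fell in 12 of 21 cases after microneedles (14 adjusted over the list alone, median −0.59, camera adjusted p = 6.6e-05, adjusted p = 0.68 with an estimated correlation). CASP14 stood at 92.5 ± 6.70 against 299 ± 59.6 FPKM (adjusted p = 0.000199) and filaggrin (FLG), which bundles keratin in the cornified layer, at 114 ± 40.7 against 314 ± 18.4 (adjusted p = 0.00123). Hair follicle markers fell in 3 of 10 cases (3 adjusted over the list alone, median −0.76, camera adjusted p = 0.0401, adjusted p = 0.724 with an estimated correlation). The follicle stem cell receptor LGR5 stood at 0.704 ± 0.132 against 2.58 ± 0.779 FPKM and the hair keratin KRT82 at 0.341 ± 0.187 against 0.727 ± 0.115 (adjusted p = 0.032). The hair follicle call ended without acne replicate 3 (adjusted p = 0.0541, median −0.41), without microneedle replicate 3 (0.101), with array weights (0.137), quantile normalization (0.0719) and fry (0.0565), and without genes that share a description (0.06). For KRT82 the call ended without acne replicates 1, 2 or 3 (0.0542, 0.08 and 0.107), without microneedle replicate 3 (0.0534), with quantile normalization (0.194), with a pseudocount of 0.1 (0.0536) and with the 6 libraries alone (0.061). Hyperproliferation-associated keratinocyte genes (2 of 13 higher, camera adjusted p = 0.996), basal keratinocyte markers (2 of 11 lower, 0.945) and cell cycle genes (1 of 26 higher, 0.551) did not pass.

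None of the 6 lipid lists passed between microneedle and untreated acne tissue. Fatty acid and triglyceride synthesis had 4 higher and 2 lower of 22 (camera adjusted p = 0.996), with SREBF1 at 22.1 ± 0.567 against 19.1 ± 1.07 FPKM (limma adjusted p = 0.15) and ACACA at 8.70 ± 0.681 against 8.38 ± 0.503 (0.742). PPARG stood at 9.28 ± 1.41 against 9.09 ± 0.878 FPKM (log2 fold change 0.02, adjusted p = 0.932), with the opposite sign without acne replicate 1 (−0.05), microneedle replicate 1 (−0.05) or microneedle replicate 2 (−0.02). DGAT2 stood at 78.3 ± 4.48 against 100 ± 11.5 FPKM (adjusted p = 0.27, and 0.0485 with the 6 libraries alone). Sebocyte and sebaceous gland markers had 3 higher of 16 (camera adjusted p = 0.758), cholesterol synthesis and uptake 4 higher and 3 lower of 22 (0.165), fatty acid oxidation and peroxisomal genes 2 and 1 of 21 (0.419), and steroid, retinoid and insulin-like growth factor signalling 2 and 4 of 19 (0.945). Of 13 lipid droplet, lipolysis and adipocyte genes, 2 were higher (camera adjusted p = 0.622). These were CD36, a fatty acid receptor, at 122 ± 36.7 against 26.4 ± 7.86 FPKM (adjusted p = 0.000891), and the lipid droplet coat protein PLIN2 (log2 fold change 1.04, adjusted p = 0.000138), both chosen after their values were seen. So were the desaturases FADS1 and FADS2, with log2 fold changes of 1.47 and 1.54.

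Endothelial and lymphatic markers rose in 5 of 18 cases and fell in 1 (5 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.044, adjusted p = 0.644 with an estimated correlation). PECAM1, an adhesion molecule of vessel walls, stood at 171 ± 5.69 against 91.6 ± 7.00 FPKM and the lymphatic receptor LYVE1 at 45.3 ± 5.63 against 18.7 ± 1.83. The call ended without acne replicates 1 or 2 (adjusted p = 0.073 and 0.0721), without microneedle replicate 1 (0.1), with TPM rescaling (0.0565), quantile normalization (0.108) and either stricter filter (0.0557 and 0.105), and without genes that share a description (0.0509). The median was 0.44 without microneedle replicate 3. Mitochondrially encoded genes fell in 9 of 13 cases and rose in 1 (9 and 1 adjusted over the list alone, median −2.31, camera adjusted p = 9.33e-07, adjusted p = 0.428 with an estimated correlation). ATP6 stood at 42.6 ± 2.62 against 7710 ± 630 FPKM and COX3 at 58.2 ± 2.59 against 4825 ± 652, while CYTB stood at 5357 ± 223 against 5695 ± 659. Other large changes were in genes at or near 0 in 1 of the groups: the membrane protein gene MS4A18 at 0.519 ± 0.194 against 26.4 ± 4.20 FPKM, the transcriptional adaptor TADA3 at 7.01 ± 0.205 against 0.103 ± 0.0239, and the prostaglandin reductase gene PGER1 at 19.5 ± 14.3 against 0.308 ± 0.175. PGER1 has 9 further genes with its description, which together stood at 66.7 ± 24.3 against 100.5 ± 4.67 FPKM.

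The other lists did not pass between microneedle and untreated acne tissue. Matrix proteases and inhibitors had 6 higher and 1 lower of 20 (camera adjusted p = 0.0809), angiogenesis and growth factor genes 5 and 2 of 21 (0.0677), and cartilage markers 1 lower of 16, with a median of −0.64 (0.101). Regulators that restrain inflammation had 3 higher and 2 lower of 16 (0.402), Toll-like receptor, NF-kB and inflammasome components 5 and 2 of 21 (0.536), and complement components 2 and 3 of 14 (0.996). Fibrillar collagen and matrix genes had 3 higher and 2 lower of 20 (0.945), proteoglycans and hyaluronan genes 2 and 4 of 23 (0.996), and antioxidant and NRF2 target genes 6 and 6 of 22 (0.402). Smooth muscle and pericyte markers had 1 higher and 2 lower of 13 (0.198), Schwann cell and nerve markers 1 and 2 of 12 (0.996), skeletal muscle markers 3 lower of 7 (0.112), melanocyte markers 1 lower of 8 (0.963) and mast cell markers 2 higher of 7 (0.906). Cytoplasmic ribosomal proteins had 3 higher and 2 lower of 70 (0.186), nuclear oxidative phosphorylation genes 3 and 2 of 27 (0.157), and immediate early and heat shock genes 2 and 2 of 17 (0.909). The immediate early and heat shock score was 0.45 and 0.67 in microneedle replicates 1 and 2 and −0.61 in replicate 3. In untreated acne it was −0.09 to 0.33. IL6 and CXCL8 were likewise lowest in replicate 3 of the microneedle group. Of 4 tested erythrocyte genes, 3 were lower. Median, mean and test differed in sign for 8 further lists, namely complement, sebocyte, fatty acid synthesis, steroid signalling, hyperproliferation, proteoglycans, mast cell and Schwann cell markers, all with absolute medians of 0.32 or less.

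The third comparison set microneedle tissue against normal skin. Most tested neutrophil, macrophage and antimicrobial genes were above normal skin after treatment, and most tested cartilage, nerve and muscle markers below it. Of these list calls, only that of the neutrophil markers held with an estimated correlation between genes. S100A12, a neutrophil calcium-binding protein, stood at 1388 ± 547 against 1.34 ± 1.49 FPKM (log2 fold change 9.33, limma adjusted p = 5.96e-07), SAA3 at 8979 ± 1258 against 13.7 ± 11.6 (9.52, adjusted p = 2.19e-07) and S100A8 at 1874 ± 965 against 3.06 ± 2.17 (8.84, adjusted p = 8.23e-07). BGLAP stood at 0.303 ± 0.319 against 79.6 ± 27.7 FPKM (−5.93, adjusted p = 7.25e-08), the cartilage collagen COL9A3 at 6.87 ± 4.70 against 145 ± 64.6 (−4.39, adjusted p = 0.000149) and PPP1R3C, which directs glycogen synthesis, at 2.98 ± 3.08 against 60.2 ± 8.05 (−4.23, adjusted p = 0.000101). In all, 3263 genes were higher and 3920 lower (50.8%), of which 1001 and 985 differed at least 2-fold. TPM rescaling moved the median log2 fold change from −0.03 to −0.17 and the calls to 2495 higher and 4991 lower, 33.3% higher in place of 45.4%.

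Neutrophil markers rose in 13 of 14 cases against normal skin (13 adjusted over the list alone, median 3.39, camera adjusted p = 3.14e-11), and Toll-like receptor, NF-kB and inflammasome components in 17 of 21 (18 adjusted over the list alone, median 1.03, camera adjusted p = 2.85e-07). Over the 3 comparisons these were the only 2 list calls that held with an estimated correlation, at adjusted p = 0.0428 and 0.0344. None of the 38 lists held in acne against normal skin or in microneedle tissue against untreated acne, where 10 and 3 lists had an unadjusted camera p under 0.05 with an estimated correlation. CSF3R stood at 8.64 ± 0.709 against 0.00661 ± 0.00573 FPKM, and MMP9 at 32.9 ± 6.86 against 0.317 ± 0.137. Macrophage and monocyte markers rose in 18 of 18 cases (18 adjusted over the list alone, median 2.56, camera adjusted p = 1.8e-11, adjusted p = 0.052 with an estimated correlation). T and natural killer cell markers rose in 11 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 0.00188, adjusted p = 0.341 with an estimated correlation). GZMA had a log2 fold change of 1.33 and the interleukin 7 receptor IL7R of 1.42. B and plasma cell markers rose in 7 of 10 cases (7 adjusted over the list alone, median 1.63, camera adjusted p = 0.000106, adjusted p = 0.318 with an estimated correlation). Dendritic and Langerhans cell markers rose in 7 of 14 cases and fell in 2 (7 and 2 adjusted over the list alone, median 0.52, camera adjusted p = 0.0375, adjusted p = 0.341 with an estimated correlation), a call that ended without normal skin replicate 2 (0.0559) and with median-of-ratios scaling (0.052).

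Proinflammatory cytokines and chemokines rose in 17 of 21 cases against normal skin (19 adjusted over the list alone, median 2.01, camera adjusted p = 1.43e-06, adjusted p = 0.318 with an estimated correlation), among them the T cell attractant CCL5 at a log2 fold change of 3.22. Regulators that restrain inflammation rose in 10 of 16 cases (11 adjusted over the list alone, camera adjusted p = 0.000139, adjusted p = 0.182 with an estimated correlation), led by IL1RN at 3.36. Interferon-stimulated genes rose in 13 of 17 cases (14 adjusted over the list alone, median 0.69, camera adjusted p = 3.51e-05, adjusted p = 0.336 with an estimated correlation), with IFIT3 at 1.39. Epidermal antimicrobial and alarm genes rose in 11 of 11 cases (11 adjusted over the list alone, median 3.57, camera adjusted p = 1.37e-08, adjusted p = 0.117 with an estimated correlation). Complement components rose in 9 of 14 cases and fell in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.000865, adjusted p = 0.117 with an estimated correlation). Matrix proteases and inhibitors rose in 16 of 20 and fell in 2 (16 and 2 adjusted over the list alone, median 1.62, camera adjusted p = 3.79e-07, adjusted p = 0.052 with an estimated correlation). Cell cycle genes rose in 21 of 26 cases (21 adjusted over the list alone, camera adjusted p = 5.13e-07, adjusted p = 0.436 with an estimated correlation). The replication helicase subunit MCM4 rose by 1.25 on the log2 scale and cyclin B1 (CCNB1) by 1.55. Hyperproliferation-associated keratinocyte genes rose in 7 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00976, adjusted p = 0.336 with an estimated correlation), a call that ended with a filter of FPKM of at least 5 (0.081).

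Mitochondrially encoded genes rose in 6 of 13 cases and fell in 1 in microneedle tissue against normal skin (6 and 1 adjusted over the list alone, median 0.64, camera adjusted p = 0.00372, adjusted p = 0.341 with an estimated correlation). COX2 stood at 4668 ± 62.2 against 30.8 ± 7.35 FPKM and ND2 at 16.99 ± 2.41 against 0.149 ± 0.119, and the median was 0.29 without microneedle replicate 3 and 0.27 without normal skin replicate 2. Cartilage markers fell in 16 of 16 cases (16 adjusted over the list alone, median −2.85, camera adjusted p = 5.13e-07, adjusted p = 0.336 with an estimated correlation). Smooth muscle and pericyte markers fell in 12 of 13 (13 adjusted over the list alone, median −1.40, camera adjusted p = 6.46e-05, adjusted p = 0.341 with an estimated correlation), with calponin 1 (CNN1) at a log2 fold change of −3.27. Schwann cell and nerve markers fell in 10 of 12 (11 adjusted over the list alone, median −1.69, camera adjusted p = 5.93e-05, adjusted p = 0.336 with an estimated correlation), with the adhesion molecule NCAM1 at −1.77. Skeletal muscle markers fell in 5 of 7 (5 lower and 1 higher adjusted over the list alone, median −1.58, camera adjusted p = 0.0268, adjusted p = 0.202 with an estimated correlation). The muscle glycogen phosphorylase PYGM had a log2 fold change of −2.37 and desmin (DES) of −1.99. The skeletal muscle call ended without a filter, where the median was −0.04 (0.0635), and with TPM rescaling (0.0805). Among the 19 lists tested that did not pass were fatty acid and triglyceride synthesis, with 2 higher and 12 lower of 22 (0.0639), cornified envelope genes, with 7 and 4 of 21 (0.266), and fatty acid oxidation and peroxisomal genes, with 9 and 2 of 21 (0.0572). Of 4 tested erythrocyte genes, 4 were lower, with a median log2 fold change of −1.70. Median, mean and test differed in sign for sebocyte, steroid signalling, mast cell and angiogenesis genes, none of which passed.

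The last comparison asked how many acne-associated genes moved back after microneedles. Of the 6167 genes that differed between acne and normal skin, 1518 (24.6%) moved the opposite way between untreated and microneedle tissue: 915 had risen in acne and then fell, as did CASP14, IL1A, JCHAIN and CD3E, and 603 had fallen and then rose, as did the acyl-CoA synthetase ACSL3, chosen after its values were seen. A further 587 (9.5%) moved again in the same direction, 294 upward, including MMP9, and 293 downward. That count was 289, 304 and 279 without acne replicates 1, 2 and 3, 382 without microneedle replicate 1, 1137 without microneedle replicate 3 and 1580 with array weights. Independent lists of these sizes would share 896 genes in opposite and 903 in the same direction. Across genes, the log2 fold changes of the 2 comparisons had a covariance of −0.10 against −0.01 in 20 simulations with unchanged groups, a difference of −0.09. Their correlation was −0.24 against −0.50 in the simulations, and 56.6% of genes had opposite signs against 66.7%. Unchanged groups hold only spread between libraries, which fixes both simulated values whatever its size. They are therefore no measure for groups that differ, and no conclusion is drawn from them. Both comparisons use the same 3 untreated libraries, which are too few to split, so part of the excess may come from those libraries. The count of opposite moves was 956 without acne replicate 1 and 845 without acne replicate 2. Of the 1518 genes, 959 no longer differed from normal skin after microneedles by the limma test, and 4335 of the 6167 acne calls (70.3%) still passed against normal skin in the same direction.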

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

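Testing the recovered fragments with voom and leaving out genes that share a description were tests chosen after the result was seen; all other settings were chosen earlier. Some genes and lists could not be tested under every setting. The filter of FPKM of at least 5 left 126 of 142 gene results and 41 of 49 list results, and a mean FPKM of at least 1 left 140 gene results. Leaving out genes that share a description, and with them the mitochondrially encoded genes, left 116 gene and 46 list results. Under the settings in which they were tested, 117 of the 142 gene results kept their call and direction and 136 never changed direction. Of the 49 list results, 39 kept their call and test direction under all of these except the estimated correlation, and 2 kept both with it as well. No list test changed direction where it was run, although the median of the dendritic list changed sign, from −0.56 to 0.04, between microneedle and untreated acne tissue with the filter of FPKM of at least 5.

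Counts followed the filter and the threshold. A filter of FPKM of at least 5 tested fewer genes and gave 1922 higher and 2100 lower genes in acne against normal skin, 1487 and 1189 in microneedle against untreated acne tissue, 2366 and 2210 in microneedle tissue against normal skin, and 960 opposite moves. More of the calls were then higher than lower in the last 2 comparisons (55.6% and 51.7% higher, against 46.2% and 45.4%). With an absolute log2 fold change of at least 1 added to the adjusted p, the counts in those comparisons were 1028 and 731, 261 and 367, and 1001 and 985, with 233 opposite moves. With the unadjusted p in its place they were 1038 and 737, 271 and 391, and 1006 and 987, with 248 opposite moves. At an adjusted p under 0.01 there were 2078 higher and 2006 lower genes in acne, 821 higher and 946 lower in microneedle against untreated acne tissue, and 645 opposite moves. Fewer genes tested or a stricter threshold give smaller counts by construction, while for the turned balance of higher and lower calls the cause was not tested. TPM rescaling gave 4869 lower genes in acne. It divides each library by the FPKM total of its tested genes. Over all genes the total was 435974 to 466599 in normal skin and 493889 to 521549 in untreated acne. The rescaling therefore lowers acne values against normal skin by construction. Part of the gap in totals lies in mitochondrially encoded genes, whose values are uncertain, such as COX2 at 8450 FPKM in untreated acne against 30.8 in normal skin. Array weights gave 3279 higher and 3838 lower genes in microneedle against untreated acne tissue and 2960 opposite moves. For array weights the cause was not tested.

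Leaving out 1 library at a time gave 1072 to 2777 higher and 1292 to 3130 lower genes in microneedle against untreated acne tissue, and 845 to 2112 opposite moves. In that comparison the log2 fold changes of genes that did not pass and changed sign ran from −0.22 to 0.63 for TNF, −0.29 to 0.54 for S100A8, −0.051 to 0.139 for PPARG, −0.065 to 0.809 for KRT16 and −0.164 to 0.065 for TGFB1. TNF was −0.032 with a pseudocount of 0.1 and −0.083 with voom, COL1A1 0.13 with quantile normalization and TGFB1 0.034 with array weights. For these sign changes the cause was not tested.

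Replicate numbers were also fitted as a replicate block, which gave 2755 higher and 2987 lower genes in acne against normal skin, 1611 and 1932 in microneedle against untreated acne tissue, 3097 and 3702 in microneedle tissue against normal skin, and 1293 opposite moves. The block ended the calls of ACACA in acne (adjusted p = 0.0769) and KRT82 after microneedles (0.0587) and changed no other call of a named gene. Residuals of samples with the same number correlated at −0.218 to 0.07, so the numbers gave no sign of pairing. The planned count tests for a table of counts were not run because the table holds FPKM. With 3 libraries per group, 62.1% of 66 simulated 1.5-fold changes were recovered, a rate that need not hold for the data, where far more genes passed. Small changes among the genes that did not pass stay open.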

Other observations

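Tests of the 3 patterns weighed below were chosen after the result was seen, and tests of other groupings of the libraries were chosen earlier. Enrichment tests of microneedle against untreated acne tissue gave 15 terms among the higher and 32 among the lower genes. Of the 15, 6 are given here, chosen after their values were seen, including neutrophil degranulation (45 of 167 members higher, 23 from chance, Fisher exact adjusted p = 0.0031) and binding of sperm to zona pellucida, a term that holds chaperonin subunits (10 of 13, 1.79 from chance, adjusted p = 0.00121). Ribosome biogenesis had 27 of 77 members higher (10.6 from chance, Fisher exact adjusted p = 0.00252), with the nucleolar protein NOP58 at 35.2 ± 9.20 against 19.0 ± 0.662 FPKM (mean ± SD, n = 3). Cytoplasmic ribosomal proteins, a separate list, did not pass, with 3 higher and 2 lower of 70 (camera adjusted p = 0.186). Proteasome had 19 of 46 members higher (6.34 from chance, adjusted p = 0.0031), including the catalytic subunit PSMB1 at 142 ± 21.4 against 97.8 ± 3.09 FPKM. Protein folding had 28 of 96 members higher (13.2 from chance, adjusted p = 0.0232), with the chaperonin subunit CCT4 at 104 ± 28.1 against 54.2 ± 4.30 FPKM. FKBP5, a co-chaperone of steroid receptors, stood at 78.7 ± 57.1 against 13.4 ± 1.23 FPKM. Cholesterol metabolism had 13 of 33 members higher (4.55 from chance, adjusted p = 0.0448). Its members ANGPTL4, an inhibitor of lipoprotein lipase, and NPC1, a lysosomal cholesterol exporter, had log2 fold changes of 2.63 and 1.01. These genes were chosen after their values were seen.

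Against normal skin, microneedle tissue had lower transcripts of the cilium, 64 of 119 members (32.4 from chance, Fisher exact adjusted p = 9.87e-07), and of smoothened signalling, the hedgehog pathway of follicle and gland development, 29 of 48 (13.1 from chance, adjusted p = 0.000655). The hedgehog co-receptor BOC stood at 14.9 ± 5.76 against 48.5 ± 12.2 FPKM and the ligand DHH at 0.400 ± 0.0135 against 3.44 ± 1.94. In untreated acne BOC stood at 18.2 ± 1.42 and DHH at 0.815 ± 0.214 FPKM, so most of both differences was present without microneedles. Microneedle replicate 3 had 111 genes over 2-fold above and 122 over 2-fold below both other microneedle libraries. The transcription factor FOS stood at 6.58 FPKM there and at 118 and 164 in the others, the prostaglandin enzyme PTGS2 at 1.12 against 15.3 and 18.6, and the monocyte attractant CCL2 at 10.6 against 102 and 124. The barrier protein FLG2 stood at 38.4 FPKM against 9.96 and 8.43, and the decoy receptor IL1R2 at 149 against 43.8 and 45.6. BOC, DHH and the genes of replicate 3 were chosen after their values were seen.

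The first pattern was genes present in every library of 1 group and nearly absent from every library of another. A lower yield of all mitochondrial transcripts after microneedles was argued against, because 3 mitochondrially encoded genes moved by under 0.5 on the log2 scale. A mitochondrial sequence variant carried by the animals of a group could also account for it, and cannot be told apart from a group effect. Pairs of an untreated and a microneedle library differed in at least 4 such genes and pairs within a group in at most 1. The pattern was defined by genes that differ between every such pair, so the 4 follows from that choice and is no test of a variant. Among nuclear genes, 7 of 18 such genes between untreated acne and microneedle tissue shared a description with another gene, against 461 of all 8315 nuclear genes that reached 5 FPKM, these 18 included (Fisher exact p = 2.87e-05), so reads shared between near-identical copies may explain part of them. From untreated acne to microneedle tissue the other LDHA gene fell from 157 ± 20.5 to 128 ± 13.9 FPKM as LDHA rose. The other PGER1 genes fell from 100.5 ± 4.67 to 66.7 ± 24.3 as PGER1 rose. By contrast, the other lysozyme C genes rose together with LOC100341160, from 21.2 ± 6.11 to 116 ± 42.6. A ribosomal protein L34 gene (LOC127489420) fell from 228 ± 23.4 to 2.04 ± 0.517, and its 4 other genes did not rise (3.3 and 2.0). Read alignments to each copy, not analysed here, would test both a variant and shared reads.

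The second pattern was neutrophil markers higher and lymphocyte markers lower after microneedles. A lower share of the main tissue cells would move both lists alike, but the neutrophil minus T and natural killer cell score moved by 2.15 (SD 0.17, n = 3), and the neutrophil minus B cell score by 1.86 (SD 0.25). These gaps restate the pattern, which was picked because the lists moved apart, so they are no separate test. A single library did not set the pattern: leaving out each of the 6 libraries in turn ended 0 calls of the neutrophil and T cell lists by camera, with highest adjusted p = 0.000191 and 1.68e-07. Both lists had adjusted p = 0.336 with an estimated correlation, so this holds for the preset correlation alone. One hypothesis is that repeated needle injury recruited neutrophils while lymphocytes declined. Cell counts in sections could test the change of the cells but not its cause. No group received another kind of microneedle, so injury cannot be told apart from other effects of HMC-PEP MN. Group and animal differences cannot be told apart here either.

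The third pattern was cartilage, Schwann cell and smooth muscle markers lower in acne tissue. An equal dilution of all resident cells by infiltrating cells would lower the markers of all of them alike. The cartilage score minus the basal keratinocyte score moved by −2.20 (SD 0.13, n = 3) and that of Schwann cells by −1.81 (SD 0.3), so these markers fell unequally. For smooth muscle an unequal fall could not be decided (−0.99, SD 0.54). The lists were picked because they fell, and the basal list was already seen not to pass. These gaps therefore restate the list results and are no separate test of dilution. A different depth or place of the tissue piece may account for the cartilage score, which moved by −2.30, and the transcripts alone cannot decide it. Stained sections that include the cartilage plate could test it.

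Other groupings of the libraries gave a check on chance. Of the 10 ways to split the 6 libraries of a comparison, too few for a share under 0.05, 1 gave as many called genes as the real one in acne against normal skin (6167), 1 in microneedle against untreated acne tissue (4129) and 1 in microneedle tissue against normal skin (7183), the real split itself. The highest other limma counts were 0, with 560, 1192 and 1538 genes at an unadjusted p under 0.05. For lists by camera, as many calls came from 4 of 10 splits in acne against normal skin (20 real, 25 highest other), 8 of 10 in microneedle against untreated acne tissue (10 and 15) and 1 of 10 in microneedle tissue against normal skin (19 and 16). Numbers of called lists therefore do not separate the groups in the first 2 comparisons, and 10 splits are too few to decide the third. Other splits, which mix the groups, still called 16 to 25, 7 to 15 and 12 to 16 lists in the 3 comparisons. A list call by camera at the preset correlation is therefore weak evidence by itself of a difference between the groups. For opposite moves, 4 of 100 drawn groupings gave at least 1518, with 3461 the highest other, and the 3 others kept all 3 libraries of 1 real group in the shared role.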
